A study of Mus musculus with 2 samples.

How the data were processed

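The samples were 2 pooled libraries of single nuclei from mouse prefrontal cortex. Per the labels' protocols, whole litters of C57BL/6J mice were randomised on the first postnatal day (P1) and the pups of a litter were divided between maternal separation and control. Male mice were taken at postnatal day 13 (P13) or 70 (P70), 4 per group as planned, and each pool was meant to hold 2 mice of each of the 4 groups. Prefrontal tissue was taken with a punch and frozen, nuclei were purified over an iodixanol cushion and stained with hashtag antibodies, and 8 mice per pool were loaded together on the 10x Chromium platform and sequenced on an Illumina NovaSeq. The litter of each mouse is not given in the sources used here, so litter could not enter any model.

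The submitters' processing notes name Cell Ranger 6.0.0, kallisto 0.46.0, bustools 0.39.3 and the mouse build mm10 without saying which step each served. The deposited matrices hold UMI counts per gene and barcode, as whole numbers, for 32285 genes and 67567 barcodes; 78 symbols occur more than once and were kept apart by identifier. The deposited hashtag tables hold raw counts per tag and barcode. Per the deposited readme, the authors called the hashtags, the cell types and the clusters, and left out hashing doublets, hashing negatives, the barcodes of a mouse found to be female and barcodes with too many Xist UMIs. In the deposited cell table these were 6911, 26291, 1169 and 430 barcodes, and 32766 (48.5%) remained; no remaining barcode held more than 2 Xist UMIs. The authors' names for mice, groups, classes and clusters were used unchanged and nothing was clustered again. How the authors normalised the data for clustering is not given in the sources used here, and it does not enter the values, which start from the raw counts.

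The 32 clusters were merged by their names into inhibitory neurons, excitatory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors and microglia; endothelial and unannotated nuclei were not among the classes fixed in advance and were not tested. Each cluster was checked for markers of its class among its 10 leading genes. Several held 0 of them. The marker lists were short, so a 0 alone does not count against a cluster's name. Microglia_12 had 0 but led with Inpp5d, Siglech and Dock8, and Oligo_14 had 0 but led with Prr5l and Aspa. Oligo.2_28, led by Bnc2, Slc47a1, Adamtsl3 and Tbx15, and Astro.3_31, led by Dnah12, Tmem212 and Cfap299, had 0 too. All clusters stayed in the class of their name, so a class can hold mixed cells. Oligo.2_28 made up 19.0 ± 3.81% of the oligodendrocytes of P13 controls. The raw counts of a mouse's nuclei in a class were summed, so that the mouse is the replicate and nuclei are not. A mouse entered a class with 10 or more nuclei, and every mouse did: it gave 566 to 1613 excitatory, 429 to 1066 inhibitory, 85 to 228 astrocyte, 58 to 238 oligodendrocyte, 16 to 125 precursor and 34 to 97 microglial nuclei. Depth per mouse was 21768476 to 62514698 UMIs. Floors and intervals cover counting error only.

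Genes were tested with edgeR 4.0.16 (R 4.3.3): TMM normalisation, filterByExpr by group, robust quasi-likelihood fits with a mean per group and a pool term over all 15 mice, and Benjamini-Hochberg adjustment at 0.05 within a class and comparison. The comparisons were separated against control at P13 and at P70, P70 against P13 in controls, and the difference between the P70 and P13 effects of separation, planned for the neuronal classes and added for glia after the first results were seen. DESeq2 1.42.0 gave a second test. Levels in the text are TMM-normalised counts-per-million (CPM). Subtypes were tested in clusters where at least 3 mice of every group held 20 or more nuclei.

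Gene lists were fixed before the data were examined and tested with limma 3.58.1 on voom weights: camera with a preset correlation of 0.01, camera with a correlation estimated from the data, and fry, adjusted over the lists within a class and comparison. A list needed 3 measured members. The 25 lists were GABA-A receptor subunits; GABA synthesis, transport and GABA-B receptors; serotonin receptors and transporter; ionotropic and metabotropic glutamate receptors; dopamine, noradrenaline and acetylcholine receptors; voltage-gated potassium channels; voltage-gated sodium and calcium channels; immediate early genes; glucocorticoid-responsive genes; stress and social neuropeptide signalling; perineuronal net and extracellular matrix; myelin genes; synaptic adhesion; axon guidance; immature neuron genes; synaptic vesicle and release machinery; the nuclear-encoded respiratory chain; heat shock, mitochondrially encoded and ribosomal protein genes as signs of RNA quality; sex-linked genes; and markers of striatal projection neurons, of choroid plexus and ependyma, and of blood and immune cells. Class shares were compared by exact two-sided permutation over all splits of the mice of an age, adjusted over classes and ages; 4 against 4 mice allow 70 assignments and 4 against 3 allow 35, so 0.0286 is the smallest p in both.

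The genes named in the text follow a rule set before the data were examined. For separation these were, per class, the 12 largest rises and 12 largest falls past the threshold with a mean of 5 CPM or more, or the 3 smallest p where 0 passed; for age, the 10 largest rises and falls with a mean of 20 CPM or more. Up to 4 members per list that passed over all genes or within the list alone were added, with Fkbp5, Nr3c1, Htr1a, Htr2a, Htr3a, Gabra5, Slc12a5, Pvalb, Sst and Vip whatever their p, and Xist and Ddx3y per group. Predicted and clone-named gene models were counted and not named. Among the genes that the rule names, 2 are not reported here. Of these genes the text gives the values of those that describe each comparison and leaves the others in its counts. Positions are from the GENCODE annotation of mm10, in which 99.6% of the gene identifiers were found.

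The alternatives planned before the data were examined were DESeq2's size factors in the same fit, DESeq2's own test, no filter on low counts, no pool term, replicate number as a block, mice of an age alone, each mouse's class sum thinned to the smallest, a minimum of 50 nuclei, leaving out the 5% of nuclei with the most UMIs, adjustment over the 6 classes together, and each mouse left out in turn. Fits within each pool, fits on chosen clusters or with equal cluster makeup, and all tests of the difference between ages in glia were added after seeing the data. Every model result was also set against other splits of the same mice, all 35 where there were that many and 100 drawn at random for the difference between ages. The pipeline was tested on simulated data in which 200 genes per class, all at 5 CPM or more, were changed 1.5-fold or 2-fold. The simulated counts held no pool, age or cluster structure. At P13 it recovered 96% and 100% in excitatory neurons, 56% and 79% in astrocytes and 23% and 52% in oligodendrocytes, with 0 calls of the wrong sign. False calls at P13 were 12 of 205 in inhibitory neurons, 4 of 222 in excitatory neurons and 7 of 155 in astrocytes. They were 3 of 82 in oligodendrocytes, 11 of 111 in precursors and 9 of 95 in microglia. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The authors' layout of the nuclei was not used here.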

Results

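The data describe the prefrontal cortex of male C57BL/6J mice after maternal separation in early life, a model of early-life stress. Nuclei from frozen tissue punches were profiled by single-nucleus RNA sequencing in 2 pools of 8 mice, in which antibody hashtags told the mice apart. The mice fell into 4 groups: control and separated pups taken at postnatal day 13 (P13), and control and separated adults taken at P70. Each P13 group and the P70 control group held 4 mice, 2 in each pool. The P70 separated group held 3 mice, because the submitters left out a mouse of pool 2 that proved to be female. The mouse was the replicate throughout.

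Of 67567 barcodes in the deposited count tables, 32766 carried a mouse name and a place in the authors' annotation of 32 clusters. These nuclei gave 1339 to 2861 nuclei per mouse and 21768476 to 62514698 UMIs per mouse (UMI, a unique molecular identifier that marks 1 captured transcript). The median nucleus of a mouse held 13065 to 24232 UMIs and 4452 to 5749 genes. A gene with 3 counts in a whole mouse would stand at 0.0480 to 0.138 CPM (counts-per-million). The sum of a single class is smaller, so 3 counts stand at a higher CPM there. P13 controls gave 2395 ± 149 nuclei (SD, n = 4 mice) and 53.5 ± 7.53 M UMIs (M, mega), and P13 separated pups 2461 ± 395 nuclei and 49.4 ± 6.55 M UMIs. P70 controls gave 2228 ± 258 nuclei and 39.1 ± 6.37 M UMIs, against 1477 ± 181 nuclei and 27.5 ± 5.08 M UMIs in the 3 P70 separated mice. The lower nuclei number in P70 separated mice had an exact two-sided permutation p of 0.0286, the smallest that 4 against 3 mice can give, with 2229 against 1511 nuclei in pool 1 and 2228 against 1410 in pool 2. Ddx3y, a Y-linked gene, stood at 34.3 ± 1.36 CPM in P13 controls, 36.2 ± 2.41 in P13 separated pups, 40.3 ± 1.86 in P70 controls and 38.5 ± 1.53 in P70 separated mice. Xist, the RNA of the inactive X chromosome, stood at 0.319 to 0.705 CPM per mouse in pool 1 and at 6.69 to 8.99 CPM in pool 2, the pool that held the female. Its group means were 3.79 ± 3.88, 3.90 ± 3.80, 4.51 ± 4.60 and 2.92 ± 4.40 CPM in the same order of groups. Below, a change is the log2 ratio of separated to control mice with its SE from the model, levels are mean CPM ± SD over mice, and adjusted p values come from edgeR's quasi-likelihood test within a cell class and comparison.

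The first comparison asked which transcripts separation changed in pups at P13. Excitatory neurons held most of the called genes. In them, 348 genes rose and 447 fell in separated pups among 18929 tested, with a median absolute change of 0.375 and a largest one of 2.19. The named rises included Trf, the iron carrier transferrin, which went from 13.9 ± 2.48 to 26.1 ± 11.3 CPM, and Itga11, a collagen-binding integrin subunit, which went from 15.7 ± 2.25 to 29.1 ± 10.9 CPM. The named falls included Exph5, an effector of Rab27 in vesicle transport, from 24.4 ± 2.87 to 14.4 ± 4.24 CPM, and Hist1h2be, a core histone H2B gene, from 8.76 ± 1.52 to 5.31 ± 0.911 CPM. Each named gene moved the same way in 4 of 4 separated pups against the control mean.

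Of the named rises in P13 excitatory neurons Dnah17, an axonemal dynein heavy chain, rose by 0.91 ± 0.14 (adjusted p = 0.00464) from 7.38 ± 1.6 to 14.6 ± 7.54 CPM. Trf rose by 0.87 ± 0.16 (adjusted p = 0.0155) and Itga11 by 0.86 ± 0.15 (adjusted p = 0.0128). Acr, the sperm protease acrosin, rose by 0.78 ± 0.17 from 5.73 ± 0.53 to 9.77 ± 2.42 CPM, and Klhl10, a spermatid ubiquitin ligase adaptor, by 0.62 ± 0.13 to 23.2 ± 8.66 CPM. Baiap2l1, an actin and membrane-shaping protein, rose by 0.64 ± 0.09 and Gnl3, the nucleolar GTPase nucleostemin, by 0.53 ± 0.08 (both adjusted p = 0.00447). Gnl3 went from 38.8 ± 0.656 to 56.2 ± 9.62 CPM. Arhgef33, Spata13, Zfp46, Dap and Cd226 rose by 0.53 to 0.63. Among the falls, Zmym1 changed by -0.97 ± 0.24 (adjusted p = 0.0414), Rgsl1 by -0.81 ± 0.18, Exph5 by -0.77 ± 0.14 (adjusted p = 0.0163), Katnal2 by -0.76 ± 0.19 and Hist1h2be by -0.73 ± 0.12 (adjusted p = 0.00682). Ccdc7b, Trmt2b, Kctd9, Acrbp, Hipk4, Cage1 and Cpsf4l changed by -0.72 to -0.67. Of the called genes, 80 of the rises and 78 of the falls were predicted or clone-named gene models.

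Further genes named by the rule in P13 excitatory neurons came from the gene lists or were fixed in advance. Grin1, the subunit shared by all NMDA receptors, rose by 0.32 ± 0.07 (adjusted p = 0.0276) from 414 ± 10.3 to 518 ± 78.7 CPM. Htr2a, the serotonin 2A receptor, fell by 0.29 ± 0.07 on the log2 scale (adjusted p = 0.0258) from 49.9 ± 4.77 to 41.2 ± 9.38 CPM. Grm2, a presynaptic metabotropic glutamate receptor, fell by 0.55 ± 0.11 (adjusted p = 0.0163) from 8.22 ± 0.778 to 5.59 ± 0.84 CPM. Kcna2, a Kv1 potassium channel, changed by -0.27 ± 0.07 (adjusted p = 0.0338), and Npy1r, the neuropeptide Y Y1 receptor, by -0.46 ± 0.12 (adjusted p = 0.0388). Penk, which encodes enkephalin precursors, rose by 0.26 ± 0.06 (adjusted p = 0.0188). Nnat, an imprinted gene of developing neurons, rose by 0.46 ± 0.10 to 93.7 CPM, and Ptprc, the leukocyte antigen CD45, rose by 0.74 ± 0.17 from 1.73 to 2.96 CPM. Slc12a5, the chloride extruder of mature neurons, stood at 96.2 ± 1.53 CPM in controls and 111 ± 14.8 CPM in separated pups (0.20 ± 0.06, adjusted p = 0.0788). Fkbp5, a glucocorticoid-induced chaperone, stood at 22.9 ± 2.14 against 29.9 ± 11.4 CPM (0.36 ± 0.18, adjusted p = 0.248), higher in 3 of 4 pups. Nr3c1, the glucocorticoid receptor, changed by -0.16 ± 0.12, Htr1a by -0.21 ± 0.31 and Gabra5 by 0.06 ± 0.07, none past the threshold (adjusted p = 0.472, 0.74 and 0.645).

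By the lists of related genes, fixed before the data were examined, metabotropic glutamate receptors were lower in P13 excitatory neurons. Of 7 measured members 6 were lower, 1 fell over all genes and 5 fell when adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.224 with an estimated correlation). Among the 5 were Grm2, Grm3 (-0.41 ± 0.12) and Grm7 (-0.15 ± 0.05). Of 18 myelin genes 16 were higher and Trf rose (adjusted p = 0.0143; adjusted p = 0.224 with an estimated correlation). Of the markers of other cells, 5 of 6 for oligodendrocytes (median change 0.12) and 6 of 6 for fibroblasts (median change 0.32) were higher too, 0 of them past. Nuclear-encoded respiratory chain genes were higher in 31 of 33 members and cytosolic ribosomal protein genes in 36 of 36, of which Rps27 rose (adjusted p = 6.27e-04 and 1.86e-06; adjusted p = 0.617 and 0.484 with an estimated correlation). All 10 markers of striatal projection neurons were higher, Ppp1r1b and Rgs9 past when adjusted over the list alone (adjusted p = 6.27e-04; adjusted p = 0.268 with an estimated correlation). Cluster Excit.11_24, kept in the excitatory class and led by Sh3rf2, Rarb, Rgs9 and Drd2, held 1.43 ± 0.440% of excitatory nuclei in P13 controls and 1.98 ± 1.25% in separated pups (exact permutation p = 0.657, adjusted p = 1). None of the 13 GABA-A receptor subunits (adjusted p = 0.597) and none of the 19 glucocorticoid-responsive genes (0.749) passed. The list tests also gave 0.18 for GABA synthesis, transport and GABA-B receptors, 0.456 for serotonin receptors and transporter, 0.136 for ionotropic glutamate receptors, 0.872 for dopamine, noradrenaline and acetylcholine receptors, 0.597 for voltage-gated potassium channels and 0.369 for voltage-gated sodium and calcium channels. They gave 0.358 for immediate early genes, 0.0891 for stress and social neuropeptide signalling, 0.772 for perineuronal net and extracellular matrix, 0.645 for synaptic adhesion molecules, 0.811 for axon guidance, 0.233 for immature neuron genes and 0.772 for synaptic vesicle and release machinery. The checks on RNA quality and other cells gave 0.266 for heat shock genes, 0.136 for mitochondrially encoded genes, 0.749 for sex-linked genes, 0.872 for choroid plexus and ependyma and 0.119 for blood and immune cells.

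**Figure D1:**
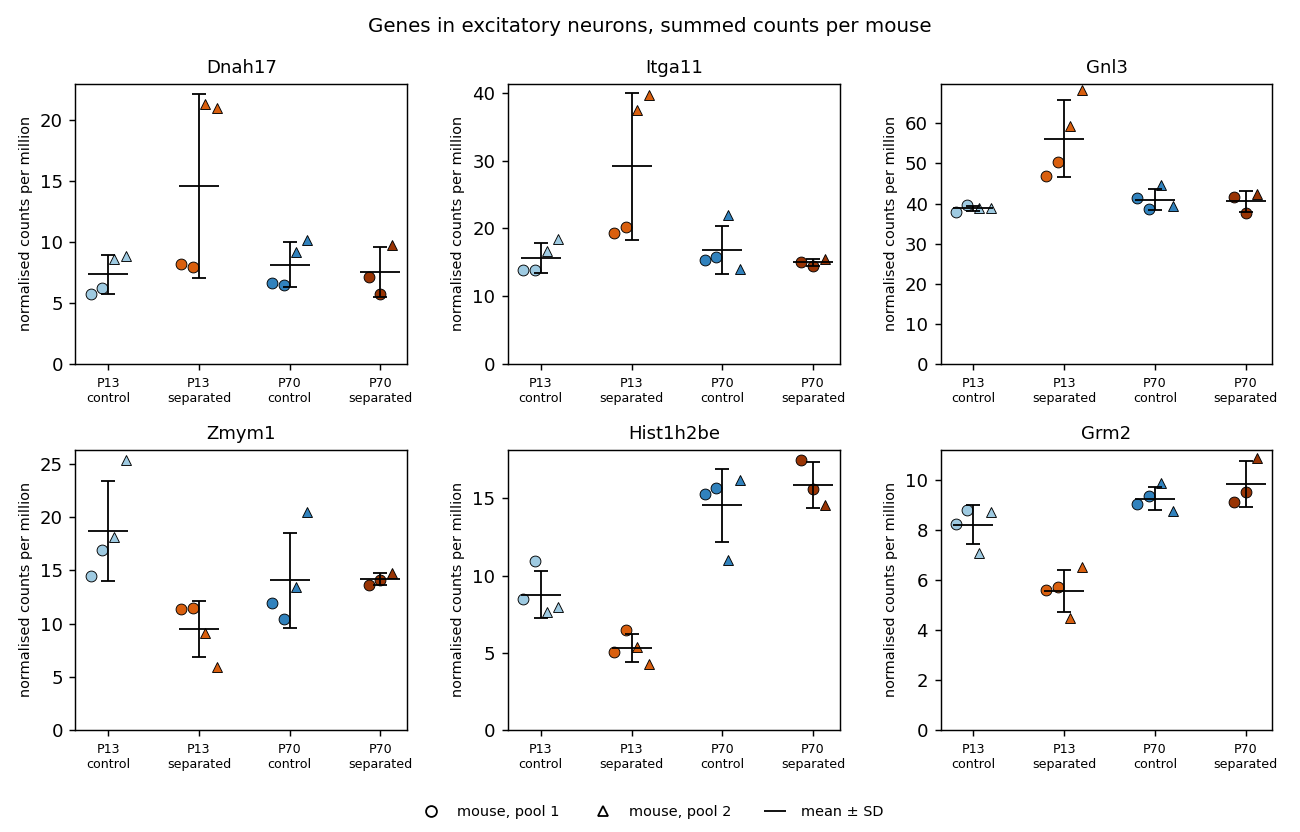
CPM of named genes in excitatory neurons for each mouse, with circles for pool 1, triangles for pool 2 and bars for the group mean ± SD. The means of Dnah17, Itga11 and Gnl3 are higher and those of Grm2, Hist1h2be and Zmym1 lower in P13 separated pups than in P13 controls.

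All 795 genes had the same sign in both pools, but within a pool the test called 0 genes in pool 1 (1490 at an unadjusted p under 0.05) and 984 in pool 2. Genes were called from both pools together, here and in the other classes, and that choice favours a shared sign. The median absolute changes of the 795 were 0.282 and 0.468, and a test of the difference between pools called 0 genes (1447 unadjusted). For example, Trf changed by 0.49 in pool 1 and 1.16 in pool 2, Htr2a by -0.13 and -0.47, Grin1 by 0.15 and 0.48, Grm2 by -0.59 and -0.50, and Hist1h2be by -0.75 and -0.70. The count fell to 22 with no pool term in the model, and to 158, 167, 186 and 200 when P13 control pool 2 replicate 2, pool 1 replicate 2, pool 2 replicate 1 or pool 1 replicate 1 was left out. It was 375 without P13 separated pool 2 replicate 2, 139 in a fit of the P13 mice alone, 119 when adjusted over the 6 classes together and 363 when every mouse's class sum was thinned to the smallest.

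In P13 inhibitory neurons 6 genes rose and 7 fell among 17865 tested. Acr rose by 0.88 ± 0.15 (adjusted p = 0.0412) from 7.71 ± 1.06 to 14.2 ± 2.6 CPM and Dnah17 by 0.68 ± 0.13 (adjusted p = 0.0412), both of which also rose in excitatory neurons. Nnat rose by 0.37 ± 0.07 (adjusted p = 0.0413) from 147 ± 16.4 to 190 ± 11.9 CPM, and Tmem165, a Golgi ion transporter, by 0.34 ± 0.06. Hist1h2be fell by 0.85 ± 0.12 on the log2 scale (adjusted p = 0.00795) from 13.9 ± 2.09 to 7.67 ± 1.53 CPM, as in excitatory neurons. Kiz, a centrosome protein, changed by -0.57 ± 0.10, Bicd2, a dynein adaptor, by -0.53 ± 0.09 (adjusted p = 0.0365), Wdr78 by -0.50 ± 0.09, and Afg1l and Banp by -0.47 ± 0.08 each. All named genes moved the same way in 4 of 4 pups. The interneuron markers did not pass: Pvalb stood at 3.82 CPM in controls and 3.06 in separated pups (-0.33 ± 0.20, adjusted p = 0.472), Sst at 69.2 and 68.8 (-0.01 ± 0.08, adjusted p = 0.971) and Vip at 24.3 and 22.2 (-0.13 ± 0.23, adjusted p = 0.838). Htr3a, the serotonin-gated channel, stood at 1.65 and 1.43 CPM (-0.19 ± 0.34, adjusted p = 0.842).

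Of the gene lists, cytosolic ribosomal proteins (36 of 36 higher) and striatal projection neuron markers (10 of 10 higher) passed in P13 inhibitory neurons, both at an adjusted p of 0.0016 and at an adjusted p = 0.82 with an estimated correlation. None of their members passed over all genes. The cluster Inhib_0, whose leading genes are striatal, held 35.2 ± 3.93% of inhibitory nuclei in controls and 43.8 ± 2.60% in separated pups (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.610). The other lists ran from 0.0583, for the respiratory chain and for the perineuronal net, to 0.964, for GABA-A receptor subunits and synaptic adhesion molecules. Among the 13 genes all had the same sign in both pools, with 0 called within pool 1 (842 unadjusted) and 18 in pool 2; DESeq2 called 131 genes. The count was 0 without P13 control pool 1 replicate 1, pool 1 replicate 2 or pool 2 replicate 1 and with no pool term, and 38 without P70 control pool 2 replicate 2. It was 2 without P70 control pool 2 replicate 1 or P70 separated pool 2 replicate 1, 3 and 5 without P13 separated pool 2 replicate 2 or 1, 6 without P70 separated pool 1 replicate 2, 7 without P13 separated pool 1 replicate 1 or P70 control pool 1 replicate 2 and 8 without P70 control pool 1 replicate 1.

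In P13 astrocytes 5 genes rose and 5 fell among 13471 tested. Gfap, the intermediate filament of reactive and fibrous astrocytes, rose by 1.10 ± 0.15 (adjusted p = 2.71e-04) from 21.3 ± 3.81 to 45.6 ± 4.93 CPM, a 2.14-fold difference. Mt1, a metallothionein that glucocorticoids and metals induce, rose by 0.87 ± 0.10 (adjusted p = 8.14e-05) from 70.4 ± 12.6 to 130 ± 42.6 CPM. The 3 other rises were predicted gene models. Trabd2b, a membrane protease that acts on Wnt proteins, changed by -1.54 ± 0.28 (adjusted p = 0.0273) from 20.1 ± 8.68 to 7.22 ± 4.13 CPM. Shisa9, an auxiliary protein of AMPA receptors, changed by -0.62 ± 0.08 (adjusted p = 2.71e-04) from 369 ± 40.6 to 241 ± 40.1 CPM. Syndig1, another AMPA receptor partner, changed by -0.76 ± 0.12 (adjusted p = 0.00219), Pdzrn4 by -0.64 ± 0.11 (adjusted p = 0.00974) and the serotonin receptor gene Htr1f by -0.62 ± 0.12 (adjusted p = 0.0281). Each moved the same way in 4 of 4 pups. Of these genes Gfap was mostly an astrocyte transcript, at 26.4 CPM over all mice against at most 6.89 CPM in the other classes that measured it. Shisa9, Syndig1, Htr1f and Pdzrn4 stood higher in both neuronal classes, for instance Shisa9 at 459 and 341 CPM in inhibitory and excitatory neurons against 310 in astrocytes. Trabd2b stood at 14.8 CPM in astrocytes, 48.6 in oligodendrocytes and 35.6 in excitatory neurons.

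Glucocorticoid-responsive genes were higher in P13 astrocytes of separated pups. Of 18 measured, 14 were higher, Mt1 rose, and 4 rose when adjusted over the list alone (camera adjusted p = 4.37e-05; adjusted p = 0.0873 with an estimated correlation). Beside Mt1 the 4 were Mt2, at 13.5 against 33.9 CPM (1.27 ± 0.27, adjusted p = 0.103), Klf9, at 132 against 187 CPM (0.48 ± 0.11, adjusted p = 0.103, higher in 3 of 4 pups), and Errfi1 (0.44 ± 0.16, adjusted p = 0.266). Receptor and channel lists were lower in the same cells: metabotropic glutamate receptors (7 of 7 lower, adjusted p = 6.2e-04), ionotropic glutamate receptors (16 of 17, 3.11e-05) and voltage-gated potassium channels (20 of 24, 0.00588). So were voltage-gated sodium and calcium channels (18 of 21, 0.0174), dopamine, noradrenaline and acetylcholine receptors (9 of 12, 0.021) and GABA-A receptor subunits (8 of 12, 0.0415). Axon guidance (27 of 35 lower, 7.75e-05), synaptic adhesion (30 of 36, 1.79e-04) and synaptic vesicle genes (17 of 27, 0.0462) were lower too. With the glucocorticoid list counted, the adjusted p of these 10 lists ran from 0.0873 to 0.359 with an estimated correlation. The lists on RNA quality moved as well: ribosomal protein genes were higher in 33 of 36 members, respiratory chain genes in 28 of 33 and heat shock genes in 8 of 9 (adjusted p = 2.23e-06, 4.71e-04 and 0.0462; adjusted p = 0.137, 0.0873 and 0.242 with an estimated correlation). Of 6 excitatory neuron markers measured in astrocytes 1 was higher and 0 passed, with a median change of -0.14, while 5 of 6 inhibitory neuron markers were higher, with a median change of 0.09 and 0 past. The serotonin list stood at 0.0514 with Htr1f the member that fell.

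**Figure D2:**
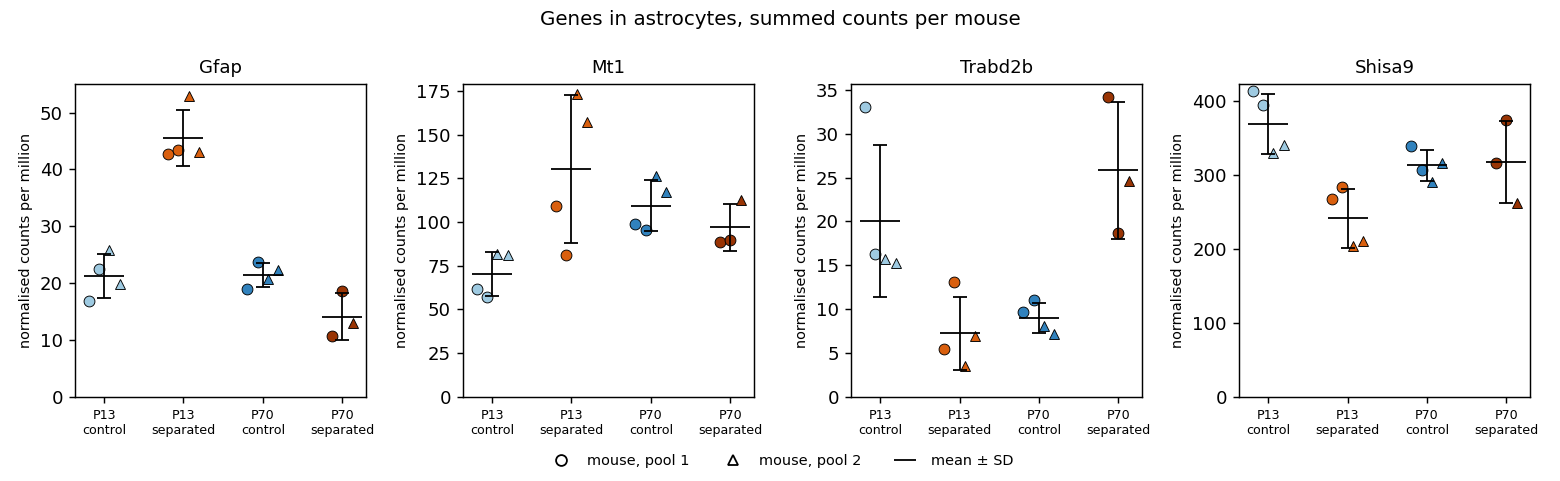
CPM of named genes in astrocytes for each mouse, with circles for pool 1, triangles for pool 2 and bars for the group mean ± SD. The means of Gfap and Mt1 are higher and those of Shisa9 and Trabd2b lower in P13 separated pups than in P13 controls.

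The test called 3 astrocyte genes within pool 1 and 53 within pool 2, and all 10 had the same sign in both; Gfap changed by 1.14 and 1.05, Mt1 by 0.69 and 1.03, Shisa9 by -0.55 and -0.69. The count was 34 without P13 separated pool 1 replicate 2, 16 without P13 control pool 2 replicate 1, 6 without P13 separated pool 2 replicate 1, 1 with no pool term and 44 by DESeq2, which shared 3 of the 10 genes.

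Few genes passed in the other glia at P13. In oligodendrocytes Arhgap24, a Rac-inactivating protein, rose by 1.26 ± 0.20 (adjusted p = 0.0172) from 21.3 ± 3.92 to 51.1 ± 8.48 CPM, and 1 predicted gene fell, among 12114 tested. Oligodendrocyte precursors held far more Arhgap24, 464 CPM, and 5 of 5 precursor markers were higher in P13 oligodendrocytes of separated pups (median change 0.16, 0 past). Without cluster Oligo.2_28, or with class sums thinned to the smallest, 0 genes passed in oligodendrocytes. In the precursors 3 genes fell among 10819. Man1a, a Golgi mannosidase, fell by 0.88 ± 0.15 on the log2 scale (adjusted p = 0.00913) from 128 ± 6.11 to 69.0 ± 15.2 CPM. Gjc3, the glial connexin Cx29, fell by 0.74 ± 0.12 (adjusted p = 0.00354) from 250 ± 25.2 to 150 ± 17.6 CPM. Cntnap5a, a contactin-associated protein, fell by 0.63 ± 0.12 (adjusted p = 0.0196) from 273 ± 33.9 to 176 ± 26.8 CPM. Over all mice Man1a stood at 97.5 CPM in precursors, 383 in oligodendrocytes and 205 in inhibitory neurons, Cntnap5a at 213 in precursors, 824 in inhibitory and 614 in excitatory neurons, and Gjc3 at 221 in precursors and 225 in oligodendrocytes. In microglia P2rx7, the ATP-gated channel, rose by 0.91 ± 0.17 (adjusted p = 0.0398) from 48.1 ± 5.2 to 91.4 ± 11.4 CPM among 11274 genes. Cdh10, a cadherin, fell by 0.66 ± 0.11 (adjusted p = 0.0176). Over all mice it stood at 451 CPM in microglia and higher in astrocytes (662), oligodendrocytes (601), excitatory neurons (585) and precursors (512). Each named gene of these glia moved the same way in 4 of 4 pups. The changes in pool 1 and pool 2 were 1.59 and 0.94 for Arhgap24, -0.78 and -0.71 for Gjc3, -0.73 and -1.05 for Man1a, and 0.79 and 1.05 for P2rx7.

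Myelin genes were lower in P13 oligodendrocytes of separated pups, in 14 of 18 members, with Gjc3 and Mobp past when adjusted over the list alone (adjusted p = 8.14e-04; adjusted p = 0.959 with an estimated correlation). In precursors 9 lists passed at an adjusted p of 2.34e-04 to 0.01, and at an adjusted p of 0.0745 to 0.422 with an estimated correlation. Of these, axon guidance (26 of 35 members), voltage-gated sodium and calcium channels (20 of 21), metabotropic glutamate receptors (6 of 6) and synaptic adhesion (26 of 36) were lower. So were voltage-gated potassium channels (19 of 24), GABA-A receptor subunits (9 of 12) and striatal markers (8 of 9). Respiratory chain (29 of 33) and ribosomal protein genes (30 of 36) were higher there. Of the markers of other cells in precursors, 5 of 5 for astrocytes (median change 0.40) and 4 of 5 for committed precursors (median change 0.30) were higher, 0 of them past. In microglia myelin genes were higher in 16 of 16 members (adjusted p = 4.01e-06; adjusted p = 0.213 with an estimated correlation), and 6 of 6 oligodendrocyte markers were higher with a median of 0.66 and 0 past. Ribosomal (35 of 36), respiratory chain (29 of 33), heat shock (8 of 8) and striatal genes (9 of 10) were higher in microglia, and potassium channels (21 of 24) and synaptic adhesion (28 of 36) were lower. Their adjusted p ran from 6.11e-10 to 0.00196, and from 0.0757 to 0.21 with an estimated correlation. Single mice moved these counts. The count in oligodendrocytes was 0 without P13 control pool 1 replicate 1 or 2, P13 control pool 2 replicate 1, P13 separated pool 1 replicate 1 or P13 separated pool 2 replicate 2, 6 without P13 separated pool 1 replicate 2, and 1 without P13 control pool 2 replicate 2, P70 control pool 1 replicate 1 or 2, P70 control pool 2 replicate 1 or P70 separated pool 2 replicate 1. That in precursors was 0 without P13 control pool 2 replicate 2, 1 without P13 control pool 1 replicate 2 or P13 separated pool 2 replicate 1, and 5 and 7 without P70 separated pool 1 replicate 2 or P70 separated pool 2 replicate 1. With class sums thinned to the smallest it was 0. The microglial count was 0 with no pool term and without P13 control pool 1 replicate 1 or 2, P13 control pool 2 replicate 1 or P13 separated pool 2 replicate 1 or 2. It was 1 without P13 separated pool 1 replicate 1 or 2 or P13 control pool 2 replicate 2, and 4 without P70 separated pool 1 replicate 2.

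Over the 6 classes 37 of 147 list tests passed at P13, 0 with an estimated correlation and 19 with fry. The share of a pup's nuclei in each class did not differ with separation past correction. Excitatory neurons made up 49.6 ± 8.41% of nuclei in P13 controls and 47.4 ± 6.04% in separated pups, inhibitory neurons 30.8 ± 7.21% and 32.5 ± 4.98%. Astrocytes made up 7.58 ± 1.24% and 7.46 ± 0.920%, precursors 4.01 ± 0.964% and 4.45 ± 0.656%, oligodendrocytes 3.25 ± 0.814% and 2.98 ± 0.617% and microglia 2.53 ± 0.498% and 3.35 ± 0.727%. Of the excitatory clusters, Excit.06_13 held 6.93% of excitatory nuclei in controls and 5.25% in separated pups (exact permutation p = 0.0286, adjusted p = 0.610).

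The second comparison asked whether adults that had been separated as pups differed from control adults at P70. No gene passed the threshold in any of the 6 classes by edgeR or by DESeq2. With no filter on low counts edgeR called 10 genes in astrocytes, 6 in oligodendrocytes, 13 in precursors and 13 in microglia, and in a fit of the P70 mice alone 3 in astrocytes. At an unadjusted p under 0.05, edgeR gave 686 genes in inhibitory and 482 in excitatory neurons and 597 in astrocytes. It gave 450 in oligodendrocytes, 555 in precursors and 760 in microglia. Chance alone would give 893, 946, 674, 606, 541 and 564 there, in any comparison. Of genes changed 2-fold in simulated data of the same depth and mice, 99% were recovered in inhibitory and 98% in excitatory neurons, 62% in astrocytes and 28 to 50% in the other glia. Of those changed 1.5-fold, 71, 85, 36, 14, 4 and 16% were recovered, in the order of classes above. The simulated changes were set in genes at 5 CPM or more, in counts with no pool, age or cluster structure, so recovery in the real mice can be lower. The median change of the genes called in P13 excitatory neurons, 0.375 on the log2 scale, was smaller than both simulated changes.

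The genes with the smallest p at P70 are given as values, none of them past the threshold, and each pointed the same way in 3 of 3 separated mice. In astrocytes Trabd2b stood at 9.0 ± 1.7 CPM in controls and 25.8 ± 7.82 in separated mice (1.41 ± 0.32), Cdh9 at 94.9 against 62.8 and Gas7 at 110 against 158. In microglia F13a1, a coagulation factor chain made by macrophages, stood at 29.8 ± 6.76 against 5.05 ± 4.29 CPM (-2.55 ± 0.51, adjusted p = 0.300), Cpne6 at 43.5 against 83.2 (1.14 ± 0.22, adjusted p = 0.163) and Apod at 61.8 against 29.3. In precursors Nts, the neurotensin gene, stood at 25.2 ± 21.3 against 0.696 ± 1.21 CPM (-4.23 ± 0.98, adjusted p = 0.291). Of all clusters the neuronal Inhib.1_4 held the most Nts, and it made up 17.2 ± 6.75% of inhibitory nuclei in P70 controls and 8.91 ± 2.02% in separated mice. Also in precursors, Pex5l stood at 322 against 181 CPM and Cdh19 at 56.6 against 121. In oligodendrocytes Sept10 stood at 14.8 against 6.04 CPM (-1.23 ± 0.31), with Nxpe3 at -0.58 ± 0.15 and Hs6st2 at 0.54 ± 0.14. In neurons the smallest p were those of Fam20b (-0.30 ± 0.07), Dedd (0.43 ± 0.11) and Fcf1 (0.33 ± 0.09) in the inhibitory class and Ston2 (0.50 ± 0.13), Rreb1 (0.38 ± 0.10) and Col9a3 (-0.45 ± 0.12) in the excitatory class. In excitatory neurons Fkbp5 changed by 0.21 ± 0.20, Nr3c1 by -0.05 ± 0.13, Htr1a by 0.09 ± 0.39, Htr2a by 0.18 ± 0.08, Slc12a5 by 0.00 ± 0.07 and Gabra5 by -0.17 ± 0.08. In inhibitory neurons Pvalb changed by 0.24 ± 0.20, Sst by 0.11 ± 0.09, Vip by 0.00 ± 0.26 and Htr3a by 0.56 ± 0.38.

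Of the gene lists 16 of 147 tests passed at P70, 0 with an estimated correlation and 1 with fry. Myelin genes were higher in inhibitory neurons (16 of 18 members, adjusted p = 0.00152; adjusted p = 0.0692 with an estimated correlation), where 6 of 6 oligodendrocyte markers were higher too, with a median of 0.14 and 0 past. The myelin genes were lower in oligodendrocytes (15 of 18, adjusted p = 0.0029; adjusted p = 0.696 with an estimated correlation) and in microglia (16 of 16, adjusted p = 2.66e-06; adjusted p = 0.31 with an estimated correlation). In microglia 6 of 6 oligodendrocyte markers were lower too, with a median of -0.32 and 0 past. Inhibitory neurons had higher ribosomal protein (34 of 36, 4.19e-08), respiratory chain (30 of 33, 0.00229) and immature neuron genes (16 of 20, 0.0351) and lower striatal markers (10 of 10, 0.00806), each at an adjusted p = 0.741 with an estimated correlation. Cluster Inhib_0 held 39.6 ± 8.60% of inhibitory nuclei in P70 controls and 34.6 ± 10.6% in separated mice (exact permutation p = 0.514), and Inhib.2_8 held 20.7 ± 12.1 and 30.8 ± 14.7% (exact permutation p = 0.371), with an adjusted p of 1 for both. Perineuronal net genes were higher in excitatory neurons (13 of 15, 0.0377), mitochondrially encoded genes in astrocytes (12 of 12, 3.4e-04) and immediate early genes in oligodendrocytes (15 of 21, 0.0234), at an adjusted p = 0.946, 0.883 and 0.696 with an estimated correlation. In microglia respiratory chain (28 of 33), ribosomal (29 of 36) and blood and immune genes (5 of 6) were lower. Synaptic adhesion (28 of 36), potassium channel (16 of 24) and ionotropic glutamate receptor genes (13 of 17) were higher. The adjusted p of these lists ran from 3.2e-05 to 0.0364, and from 0.184 to 0.365 with an estimated correlation. No single member of these lists passed.

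Pool 2 held 1 separated adult, so its P70 values rest on that mouse; within pool 1 the test called 1 microglial gene, and within pool 2 it called 2 genes in astrocytes and 2 in precursors. Leaving out P70 separated pool 2 replicate 1 gave 4 genes in precursors and 1 in microglia. Leaving out P70 control pool 1 replicate 1 or P70 control pool 2 replicate 2 gave 2 genes and 1 gene in precursors, and leaving out P13 separated pool 2 replicate 1 gave 1 in microglia. Of the class shares, precursors made up 2.14 ± 0.243% of nuclei in P70 controls and 1.62 ± 0.377% in separated mice (exact permutation p = 0.0286, adjusted p = 0.343), with 2.22 against 1.55% in pool 1 and 2.07 against 1.77% in pool 2. Oligodendrocytes stood at 7.56 ± 2.38 and 5.47 ± 0.994% in controls and separated mice, astrocytes at 7.77 ± 1.11 and 6.73 ± 0.860%, and microglia at 2.64 ± 0.469 and 2.47 ± 0.128%. Inhibitory neurons stood at 37.7 ± 3.14 and 37.8 ± 5.07% and excitatory neurons at 40.2 ± 0.799 and 43.9 ± 6.19%, none of them past correction.

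**Figure D3:**
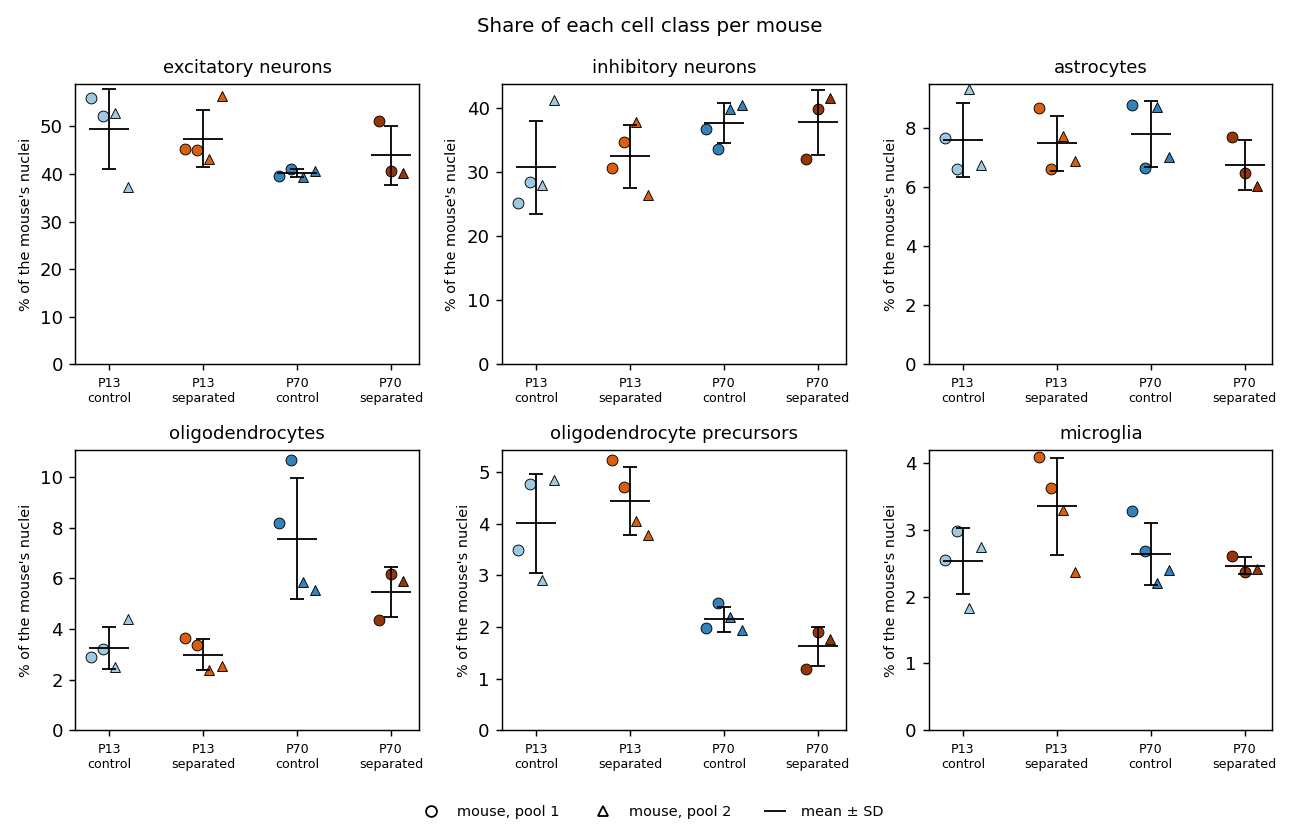
Percent of each mouse's nuclei in 6 cell classes by group, with circles for pool 1, triangles for pool 2 and bars for the group mean ± SD. From P13 to P70 the control mean of oligodendrocytes is higher and that of precursors lower, neither past correction. At each age the separated and control mice overlap in every class except the P70 precursors.

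The third comparison asked whether the effect of separation itself differed between pups and adults. It did so for 8 glial genes. In astrocytes Trabd2b changed by -1.54 at P13 and by 1.41 at P70, a difference of 2.95 ± 0.43 (adjusted p = 0.00715). Gfap changed by 1.10 and -0.54 (difference -1.64 ± 0.27, adjusted p = 0.0106), Mt1 by 0.87 and -0.09 (-0.96 ± 0.16, adjusted p = 0.0106). Htr1f changed by -0.62 and 0.40 (1.02 ± 0.18, adjusted p = 0.0123) and Pdzrn4 by -0.64 and 0.35 (0.99 ± 0.17, adjusted p = 0.0123). In oligodendrocytes Arhgap24 changed by 1.26 and -0.52 (-1.78 ± 0.30, adjusted p = 0.0412), in precursors Gjc3 by -0.74 and 0.49 (1.24 ± 0.19, adjusted p = 0.00138) and in microglia P2rx7 by 0.91 and -0.68 (-1.59 ± 0.26, adjusted p = 0.0169). In neurons the difference passed for 0 genes by edgeR, with 1675 unadjusted in the inhibitory and 2253 in the excitatory class and 3 and 44 genes by DESeq2, so a P13 change in excitatory neurons was not shown to be absent in adults. The tests in glia were added after the P13 and P70 results were seen, and those in neurons were planned. DESeq2 called 8 genes in astrocytes, 2 in oligodendrocytes, 1 in precursors and 23 in microglia. These shared 5, 1, 1 and 0 with the calls above. P2rx7 had no DESeq2 value.

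Single mice moved the number of genes whose effect differed between the ages. In astrocytes 5 genes became 2 without P70 separated pool 2 replicate 1 and 3 without P70 control or P70 separated pool 1 replicate 1. They became 8 without P13 control pool 2 replicate 1, 9 without P70 control pool 2 replicate 2 and 10 without P13 separated pool 2 replicate 2. In oligodendrocytes 1 gene passed without P13 separated pool 2 replicate 1 or P70 separated pool 1 replicate 2, 2 genes passed without P70 control pool 2 replicate 2 or P70 separated pool 2 replicate 1, and 0 without any other mouse. In precursors 2 genes passed without P13 or P70 separated pool 1 replicate 2, and 0 with class sums thinned to the smallest, which also gave 0 in oligodendrocytes. In microglia 0 passed without P13 control pool 1 replicate 1, P13 separated pool 1 replicate 2, P70 control pool 1 replicate 2 or P13 control pool 2 replicate 2. There 2 passed without P13 separated pool 1 replicate 1, P70 control pool 1 replicate 1, P13 control pool 2 replicate 1 or P13 separated pool 2 replicate 1, 9 without P70 separated pool 1 replicate 1 and 16 without P70 control pool 2 replicate 2. In inhibitory neurons 12 genes passed without P70 separated pool 1 replicate 1 and 2 without P70 control pool 2 replicate 2, and in excitatory neurons 7 without P13 separated pool 2 replicate 2 and 21 without P70 control pool 2 replicate 2. With no pool term edgeR called 0 genes in astrocytes and oligodendrocytes, and with the 5% of nuclei with the most UMIs left out it called 0 in both and 23 in microglia.

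The fourth comparison followed normal maturation in control mice from P13 to P70. It changed 5877 genes in excitatory neurons, 3001 up and 2876 down, and 2987 in inhibitory neurons, 1324 up and 1663 down. Among the named falls in excitatory neurons Met, the hepatocyte growth factor receptor, went from 38.3 ± 9.88 to 5.24 ± 1.71 CPM (-2.88 ± 0.16). Gpc5, a glypican, went from 667 ± 163 to 121 ± 28 CPM (-2.48 ± 0.18), and Dpysl5, a collapsin response protein, from 65.5 ± 13.5 to 19.5 ± 0.246 CPM (-1.75 ± 0.17). They gained Aifm3, a mitochondrial oxidoreductase, from 12.9 ± 2.98 to 80.2 ± 5.98 CPM (2.65 ± 0.13), and Epb41, a spectrin-binding protein, from 43.3 ± 10.6 to 130 ± 17.9 CPM (1.59 ± 0.13). Further falls were Klhl1, Angpt1, Gpc6, Nek10, Kcnmb2, Nckap5 and Plppr1, at -1.73 to -1.34, and further rises Smad3, Tanc1, Skap2, Specc1, Ankrd33b, Arhgef25, Cpeb1 and Sntb2, at 1.15 to 1.39.

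Axon guidance genes fell as a group with age in excitatory neurons, where 18 of 36 fell and 2 rose, among them Sema6d (-0.98 ± 0.06) and Robo1 (-0.86 ± 0.07), at an adjusted p of 4.74e-07 and an adjusted p = 0.0165 with an estimated correlation. Of 20 immature neuron genes 12 fell, including Dpysl3 (-1.18 ± 0.09), Stmn2 (-0.52 ± 0.05) and Sox11 (-0.67 ± 0.07), at an adjusted p of 4.74e-07 and an adjusted p = 0.0717 with an estimated correlation. Synaptic adhesion genes fell in 21 of 36 members (1.02e-06; adjusted p = 0.213 with an estimated correlation). Kcna1 and Kcna2 rose by 0.73 ± 0.07 and 0.59 ± 0.07, Slc12a5 by 0.26 ± 0.07 and Hapln4, a link protein of perineuronal nets, by 1.37 ± 0.17. Gabra5 fell by 0.30 ± 0.07 and the NMDA receptor subunit Grin3a by 1.01 ± 0.09. Immediate early genes rose in 13 of 25 members, such as Junb (0.81 ± 0.15), with an adjusted p of 3.02e-04 and an adjusted p = 0.585 with an estimated correlation. Of 18 myelin genes 12 rose (8.35e-06; adjusted p = 0.0165 with an estimated correlation), for instance Mobp from 7.92 to 11.8 CPM, a gene of oligodendrocytes, and 4 of 6 oligodendrocyte markers rose in excitatory neurons. Mitochondrially encoded genes were lower with age in 13 of 13 members, 4 of them past the threshold, and ribosomal and respiratory chain genes were higher (adjusted p = 0.585 for each with an estimated correlation).

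Inhibitory neurons lost Grik1, a kainate receptor subunit, from 755 ± 158 to 313 ± 46.2 CPM (-1.27 ± 0.10). They also lost St8sia2, which makes polysialic acid, from 28.4 ± 5.89 to 11.8 ± 1.14 CPM (-1.26 ± 0.15), and Elfn1, a synaptic protein of somatostatin interneurons, from 48.7 ± 10.1 to 23.9 ± 4.37 CPM. They gained Ano2, a calcium-activated chloride channel, from 14.3 ± 2.97 to 60.7 ± 12.2 CPM (2.09 ± 0.32), and Lrrk2, the Parkinson's disease kinase, from 52.1 ± 10.2 to 129 ± 13 CPM (1.32 ± 0.15). The other named rises were Onecut2, Zfp831, Tmod1, Slc24a4, Gsg1l, Lncpint, Vav3 and Cacnb2, at 0.92 to 1.49, and the other named falls Cemip, Myo3b, Adam19, Vcan, Glra2, Syt17 and Hcrtr2, at -1.18 to -0.97. Of the lists, 12 of 36 axon guidance genes and 8 of 20 immature neuron genes fell (4.75e-06 and 1.7e-06; adjusted p = 0.18 and 0.351 with an estimated correlation). The makeup of the class also differed between P13 and P70 controls: Inhib.3_9 held 17.9 ± 5.98 and 9.81 ± 0.902% of inhibitory nuclei, Inhib.4_15 7.76 ± 2.42 and 4.14 ± 0.658% and Inhib.2_8 13.1 ± 7.71 and 20.7 ± 12.1%, which was not tested. Of 6 markers of Sst interneurons 0 were higher with age, with a median of -0.75 and 3 past. In clusters Inhib.3_9 and Inhib.4_15 alone the change of Hcrtr2 was 0.08.

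Astrocytes gained Rpe65, a retinoid isomerase, from 3.52 ± 1.95 to 61.1 ± 5.96 CPM (4.16 ± 0.25), and Etnppl, an enzyme of phosphoethanolamine breakdown, from 7.82 ± 3.37 to 71.4 ± 7.46 CPM (3.24 ± 0.25). They lost Tnc, the matrix protein tenascin-C, from 145 ± 60.1 to 36.4 ± 8.32 CPM (-2.01 ± 0.39), among 358 rises and 483 falls. Oligodendrocytes gained Cntn2 (2.18 ± 0.14) and Il33 (2.07 ± 0.15) and lost Prom1 (-3.37 ± 0.35) and Casr (-3.10 ± 0.28), among 633 rises and 850 falls. Most of them came from different clusters at the 2 ages: Oligo.1_19 held 62.2% of oligodendrocytes in P13 controls and 12.5% in P70 controls, and Oligo_14 held 18.8 and 77.7%. Precursors lost Enpp6, a marker of newly forming oligodendrocytes (-1.38 ± 0.17), and Mbp, the myelin basic protein (-1.37 ± 0.26), among 111 rises and 168 falls. In the precursors 0 of 5 markers of committed precursors were higher with age (median -0.70, 4 past) and 1 of 5 of oligodendrocytes (median -0.85, 3 past). In microglia 262 genes rose and 232 fell. The rises were led by Sec14l5 and by Mog, an oligodendrocyte myelin gene, from 9.88 ± 1.33 to 70.8 ± 19.5 CPM (2.83 ± 0.27). In all, 14 of 16 myelin genes and 6 of 6 oligodendrocyte markers rose in microglia (adjusted p = 2.3e-33 for the myelin list; adjusted p = 0.0123 with an estimated correlation). Mog stood at 420 CPM in oligodendrocytes over all mice against 38.8 in microglia.

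**Figure D4:**
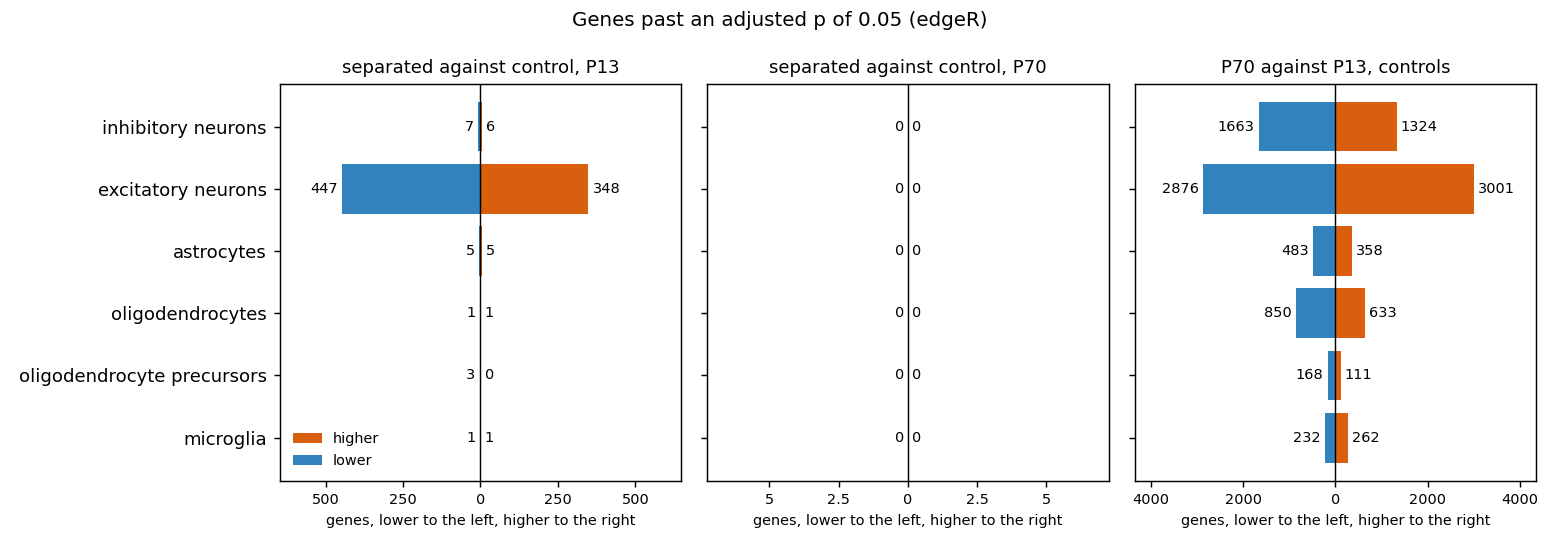
Number of genes past an adjusted p of 0.05 in each cell class, by direction, for separation at P13, separation at P70 and age in controls. Excitatory neurons hold the most genes at P13 (348 up, 447 down) and with age (3001 up, 2876 down), and separation at P70 has 0 in every class.

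The called genes kept their sign in both pools with age in all classes but for 1 of 1483 genes of oligodendrocytes. The test within pool 1 and pool 2 called 3387 and 3083 genes in excitatory neurons, 758 and 831 in inhibitory neurons. It called 253 and 233 in astrocytes, 580 and 718 in oligodendrocytes, 39 and 99 in precursors and 197 and 98 in microglia. Over the classes 51 of 147 list tests passed, 10 with an estimated correlation and 54 with fry. Excitatory cells also changed clusters with age, since Excit.00_1 and Excit.02_3 held 25.7 and 21.4% of excitatory nuclei in P13 controls but 1.15 and 0.264% in P70 controls, and Excit.01_2 and Excit.07_17 held 0.379 and 0.0839% against 41.4 and 11.7%. Among the class shares oligodendrocytes went from 3.25 to 7.56% and precursors from 4.01 to 2.14% (exact permutation p = 0.0286 for each, adjusted p = 0.0857), neither past correction.

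For the genes named first, the identifiers and mm10 positions are as follows. Gfap (ENSMUSG00000020932) lies on chromosome 11 from 102887336 to 102900912, Mt1 (ENSMUSG00000031765) on chromosome 8 from 94179082 to 94180327, Shisa9 (ENSMUSG00000022494) on chromosome 16 from 11984113 to 12270902 and Trabd2b (ENSMUSG00000070867) on chromosome 4 from 114406724 to 114615098. Trf (ENSMUSG00000032554) lies on chromosome 9 from 103204001 to 103230444, Itga11 (ENSMUSG00000032243) on chromosome 9 from 62677826 to 62783982, Htr2a (ENSMUSG00000034997) on chromosome 14 from 74640840 to 74709494, Grin1 (ENSMUSG00000026959) on chromosome 2 from 25291181 to 25319187 and Grm2 (ENSMUSG00000023192) on chromosome 9 from 106643095 to 106656082. Gjc3 (ENSMUSG00000056966) lies on chromosome 5 from 137953461 to 137963098, P2rx7 (ENSMUSG00000029468) on chromosome 5 from 122643911 to 122691432 and Arhgap24 (ENSMUSG00000057315) on chromosome 5 from 102481391 to 102897937. Trf, P2rx7, Gnl3 and Hist1h2be overlap other annotated genes on the same strand, and Hist1h2be overlaps 2 of them, so reads from these loci cannot be given to a single gene with certainty. The counts are of nuclear RNA, and how reads in introns were counted is not given in the sources used here.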

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

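Of the tests in this part, those of the difference between ages in glia, of free Xist RNA, of nuclei given to the wrong mouse and of equal cluster makeup were chosen after the result they bear on had been seen.

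Among 30 groups of mice tested for a value far from the others, 2 stood out, and chance gives about 1 in 20 groups. The mitochondrial percent of UMIs was 0.0985 in P13 separated pool 1 replicate 1 and 0.0655 to 0.0706 in the other separated pups. Excitatory neurons made up 56.4% of the nuclei of P13 separated pool 2 replicate 2 and 43.1 to 45.3% in the other separated pups.

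The effect of separation differed between the ages for 8 glial genes by the test of that difference. The log2 change at P70 minus that at P13 was 2.95 for Trabd2b, -1.64 for Gfap, -0.959 for Mt1, 1.02 for Htr1f and 0.988 for Pdzrn4 in astrocytes. It was -1.78 for Arhgap24 in oligodendrocytes, 1.24 for Gjc3 in precursors and -1.59 for P2rx7 in microglia. In astrocytes 4 of 100 drawn splits of the mice gave 5 or more genes, the real one included, and the highest other split gave 16. That share was not corrected over the glial classes, and these tests were added after results were seen. Chance therefore cannot be excluded in astrocytes. In oligodendrocytes 20 of 100, in precursors 18 of 100 and in microglia 17 of 100 splits gave 1 gene or more, with 13, 14 and 31 genes in the highest other split, so chance cannot be excluded for the number of genes there.

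Xist UMIs appeared among barcodes that the comparisons did not use. More than 2 Xist UMIs were held by 96.3% of the barcodes called as the female mouse, by 12.2% of the hashing negatives of pool 2 and by 2.49% of those called as a male mouse of pool 2, against 0.112% of the negatives and 0.0672% of the male calls of pool 1. Free Xist RNA predicted 13.6 such barcodes among the male calls of pool 2 where 419 were found, which argues against it as the whole source. A female nucleus under another mouse's hashtag would mostly lack Y transcripts, but 94.75% of the 419 had a UMI of a Y gene, against 54.1% of the Xist-high barcodes called as the female. Their share with a Y UMI was 0.964 times that of Xist-low nuclei at equal depth, consistent with droplets that held a female and a male nucleus. No biological explanation was tested, and doublets of 2 males stay unseen by this measure.

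The 795 genes called in P13 excitatory neurons were set against 3 technical explanations. With class sums thinned to the smallest, their median log2 change in the direction called was 0.367, against 0.375. Of the 795, 783 kept their direction and 310 passed. Thinning keeps each gene's expected share, so it cannot test the class sum as a cause. With equal cluster makeup the median was 0.374, 787 kept their direction and 621 passed, which argues against makeup. The weaker changes in pool 1 could come from nuclei given to the wrong mouse. The test sees adult nuclei alone: 3.66% if errors came evenly from all mice, where 39.7% would be needed. An exchange between pups of pool 1 cannot be told from a smaller effect. Separation itself, litter, dissection, hashtag and UMIs per class or nucleus stay open and were not tested.

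Other splits of the same P13 mice, 35 in all, give a measure of chance. The real split gave 13 genes in inhibitory neurons, 795 in excitatory neurons, 10 in astrocytes and 3 in precursors. The highest other split gave 7, 1, 8 and 2, and 1 split, the real one, reached each value. That is the smallest share that 35 splits can give. It was not corrected over the classes, and the splits were not held to the balance over pools. The wide gap in excitatory neurons argues against chance there. In inhibitory neurons, astrocytes and precursors the gap was small, and chance cannot be excluded. In oligodendrocytes 2 splits and in microglia 3 splits gave the 2 genes of the real one or more, the highest other gave 2 in both, and chance cannot be excluded. The 37 lists called at P13 were reached by 1 split, the real one, but the highest other gave 36 and the median other 20, so many lists pass in any split.

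At P70 the real split gave 0 genes by edgeR in every class (450 to 760 unadjusted, 0 by DESeq2). Each of the 35 splits must reach a count of 0, so their number says nothing about chance. The highest other split gave 483 genes in inhibitory neurons, 2 in excitatory neurons, 16 in astrocytes, 13 in oligodendrocytes, 14 in precursors and 62 in microglia. In 4 of the 6 classes it set P70 separated pool 1 replicate 2, P70 separated pool 2 replicate 1 and P70 control pool 2 replicate 2 against the others, which points to a structure of the samples apart from separation. The 16 lists called at P70 were reached by 27 of 35 splits, and the highest, 28, followed the pool, so chance cannot be excluded. With no pool term 13 of the 16 lists passed.

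With age in controls the real split gave 2987, 5877, 841, 1483, 279 and 494 genes in the classes in the order above. The highest other split gave 0, 0, 2, 1, 1 and 4, and 1 of 35 splits, the real one, reached each. That is the smallest share possible. The gaps were wide, but the other splits mix the ages, which adds spread, so they cannot exclude chance. The 51 lists were reached by 1 split, the real one, with 49 in the highest other. For the difference between ages in neurons the real split gave 0 genes by edgeR (1675 and 2253 unadjusted, 3 and 44 by DESeq2), which each of the 100 drawn splits must reach, so their number says nothing about chance. The highest other gave 60 in inhibitory and 14 in excitatory neurons, and whether a structure of the samples lies behind these was not tested.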

How the results depend on the processing

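The fits within pools, on chosen clusters and with equal cluster makeup, and all fits of the difference between ages in glia, were chosen after results had been seen. Of 10382 refitted values of named genes 9547 kept their direction and side of the threshold, 728 no longer passed, 67 newly passed and 40 reversed. Of 213 list values 100 kept theirs and 113 no longer passed, and of 118 class shares 105 kept their direction and 13 reversed. A minimum of 50 nuclei was not run for microglia and precursors, where too few mice were left. By the recovery in simulated data given above, 1.5-fold changes can be missed in glia at this depth. Where a setting tests fewer mice or more genes its construction changes the adjustment. Otherwise the cause was not tested.

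DESeq2's test called 131 genes at P13 in inhibitory neurons (main value 13), 44 in astrocytes (10), 1 in oligodendrocytes (2) and 1 in microglia (2). For the difference between ages it called 3 in inhibitory neurons (0), 44 in excitatory neurons (0), 8 in astrocytes (5), 2 in oligodendrocytes (1) and 23 in microglia (1).

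With no filter on low counts edgeR called 275 genes in inhibitory neurons, 194 in astrocytes, 47 in oligodendrocytes, 47 in precursors and 55 in microglia at P13. At P70 it called 10, 6, 13 and 13 in the glia in that order. With age it called 428 in precursors and 744 in microglia. For the difference between ages it called 33 in inhibitory and 45 in excitatory neurons and 56, 9, 14 and 85 in the glia as ordered above.

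With no pool term 0 genes passed in inhibitory neurons and microglia at P13, 22 in excitatory neurons, 1 in astrocytes and 1 in oligodendrocytes. With age 1799 passed in inhibitory neurons, 336 in astrocytes and 326 in microglia, and for the difference between ages 0 in astrocytes and oligodendrocytes. With replicate number as a block, although the numbers do not pair the mice, 2 genes passed in P13 inhibitory neurons. In that block the difference between ages passed for 0 genes in oligodendrocytes and 3 in microglia, and Slc12a5 at P70 in excitatory neurons reversed to 0.02.

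With mice of that age only 139 genes passed at P13 in excitatory neurons, 133 of them among the 795, 7 in inhibitory neurons, 1 in oligodendrocytes and 22 in precursors, and 3 passed at P70 in astrocytes. Vip at P70 in inhibitory neurons moved from 0 to 0.06 there. With class sums thinned to the smallest, 363 genes passed at P13 in excitatory neurons, 310 of them among the 795, 8 in inhibitory neurons and 0 in oligodendrocytes and precursors. Thinned, 423, 112 and 315 passed with age in astrocytes, precursors and microglia, and 0 for the difference between ages in oligodendrocytes and precursors. Thinning gave 0.01 for Sst at P13, 0.02 for Vip at P70 and 0 for Slc12a5 at P70.

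Without the 5% of nuclei with the most UMIs 4 genes passed at P13 in microglia, 1 at P70 in precursors and 1 in microglia. The difference between ages then passed for 0 in astrocytes and oligodendrocytes and 23 in microglia, and Sst at P13 moved to 0, Vip at P70 to 0.01 and Slc12a5 at P70 to 0. Adjusted over all 6 classes together, 119 genes passed at P13 in excitatory neurons, 25 in inhibitory neurons, 9 in oligodendrocytes, 7 in precursors and 8 in microglia. With an estimated correlation 10 gene list tests passed, against 104.

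With equal cluster makeup 115 genes passed in P13 inhibitory neurons, and the common coefficient of variation went from 0.0931 to 0.0674. That fit also left out clusters with fewer than 20 nuclei in any mouse of an age, such as Inhib.2_8 at P13. The effect of equal makeup therefore cannot be told apart from that of the missing clusters. Equal makeup gave 0.01 for Slc12a5 at P70 in excitatory neurons. With clusters Inhib.3_9 and Inhib.4_15 only, 57 genes passed at P13, 6 of them among the 13, and 1487 with age. In these clusters the change with age was 0.08 for Hcrtr2, 0.17 for Adra1b, -0.07 for Klf9, -0.28 for Gpd1, -0.29 for Fa2h and -0.15 for Sv2c, each opposite to the class, and Sst at P13 was 0.01. Without clusters Excit.08_18 and Excit.11_24 Slc12a5 was 0.01 at P70. Without cluster Oligo.2_28 0 genes passed in oligodendrocytes at P13 and for the difference between ages. With neurons only as denominator the share of inhibitory neurons at P70 differed by -2.04 points, separated minus control, against 0.0870 of all nuclei.

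Within pool 1 0 genes passed at P13 in inhibitory neurons, excitatory neurons, precursors and microglia, 3 in astrocytes and 1 in oligodendrocytes, and 1 at P70 in microglia. With age 758, 3387, 253, 580, 39 and 197 passed there in inhibitory and excitatory neurons, astrocytes, oligodendrocytes, precursors and microglia. Within pool 2 53 passed at P13 in astrocytes, 1 in oligodendrocytes, 5 in precursors and 6 in microglia, and 2 at P70 in astrocytes and 2 in precursors. With age 831, 3083, 233, 718, 99 and 98 passed in pool 2, in the same order of classes.

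With 1 mouse left out in turn the genes called at P13 ran from 0 to 38 in inhibitory neurons, 158 to 1125 in excitatory neurons, 6 to 34 in astrocytes, 0 to 6 in oligodendrocytes, 0 to 7 in precursors and 0 to 4 in microglia. At P70 they ran from 0 to 4 in precursors and 0 to 1 in microglia and stayed at 0 in the other classes. With age they ran from 2064 to 3618, 4697 to 6982, 530 to 981, 1071 to 1603, 161 to 313 and 301 to 520. The classes are in the P13 order. For the difference between ages the ranges were 0 to 12, 0 to 21, 2 to 10, 0 to 2, 1 to 2 and 0 to 16 in that order. With age the astrocyte count was 556 without P70 control pool 1 replicate 2 and 530 without P70 control pool 2 replicate 1. The precursor count was 182, 161 and 164 without P13 control pool 1 replicate 2, P13 control pool 2 replicate 2 and P70 control pool 2 replicate 1, and the microglial count 301 and 325 without P13 and P70 control pool 1 replicate 2.

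Leaving out a mouse reversed small changes that had not passed. In inhibitory neurons at P13 Htr3a ran from -0.67 to 0.02, Sst from -0.10 to 0.07 and Vip from -0.34 to 0.02, and Vip at P70 from -0.17 to 0.11. In excitatory neurons at P70 Nr3c1 ran from -0.15 to 0.02, Htr1a from -0.20 to 0.32 and Slc12a5 from -0.06 to 0.06. Differences in share at P13 ran from -0.156 to 5.24 points for inhibitory neurons, -6.23 to 0.0507 for excitatory neurons, -0.512 to 0.463 for astrocytes and -0.515 to 0.116 for oligodendrocytes. At P70 they ran from -1.79 to 2.97 for inhibitory neurons and -0.324 to 0.0357 for microglia, and 0 class shares passed correction in any of these fits.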

Other observations

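The test of maturity, the test of nuclei given to the wrong mouse, the list for cluster Inhib_0 and the fits with equal cluster makeup were chosen after results they bear on had been seen.

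Single clusters of neurons, tested as in the classes, gave 224 calls over 8 clusters at P13 and 4 at P70. A gene called in several clusters counts in each, and the 224 calls were of 185 different genes. The GABAergic cluster Inhib_0, led by striatal genes, held 114 of the calls at P13, 40 up and 74 down, and 10 of the 13 genes called in the whole inhibitory class were called there. The other inhibitory clusters held fewer: 20 genes in Inhib.3_9 and 2 in Inhib.4_15, and 0 in Inhib.1_4 (857 at an unadjusted p under 0.05). Among the excitatory clusters Excit.03_5 gave 31 genes, Excit.06_13 22, Excit.05_10 21 and Excit.04_6 14, and 22, 16, 19 and 13 of these were also called in the excitatory class. Of the 35 splits of the P13 mice only the real one, 1 split, reached 224 calls, the smallest share possible. The highest other split gave 175, so the test does not exclude chance. At P70 12 of 35 splits gave 4 or more calls, the highest 16, so chance cannot be excluded there.

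Hashtag support varied between mice, and no test of the groups was run. The called tag was also the tag with the most raw counts in 96.5% of the nuclei of a P13 control mouse and 75.9% of a separated pup's, and in 95.8% against 54.0% at P70, with 18.9% in P70 separated pool 2 replicate 1. It was 92.3 to 100% in the single P13 controls against 52.5 and 67.1% in the separated pups of pool 1 and 85.9 and 98.1% in those of pool 2, and 53.0 and 89.9% in the P70 separated mice of pool 1. Raw tag counts are not corrected for how brightly each tag stains. Each tag's share of counts was higher in its own mouse than in its pool's others. Mice were named by tag, so this is no check. In the 4 excitatory clusters filled almost wholly by mice of 1 age, 0.622 to 2.26% of nuclei carried the other age's name. Of these 100% had a Y UMI, but every mouse kept was male, so it is no check.

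Several clusters of the neuronal classes led with genes of neighbouring regions rather than of cortex. Against marker lists, Inhib_0 stood 4.54-fold above all other nuclei in the median of 10 striatal projection neuron genes and ranked 1 of 32 clusters, Excit.08_18 stood 3.95-fold above in mitral and tufted cell genes of the olfactory bulb (rank 1), and Inhib.1_4 stood 3.23-fold above in lateral septum genes (rank 1). These values are consistent with punches that reached striatum, olfactory bulb and septum, and a cortical origin with the same genes was not tested. For Inhib.2_8 olfactory bulb interneuron genes stood at 4.16-fold but Inhib.5_16 ranked above it, so the source of Inhib.2_8 was left open. Inhib_0 made up 35.2% of inhibitory nuclei in P13 controls and 43.8% in separated pups, against 17.9 and 15.6% for Inhib.3_9 and 7.76 and 7.88% for Inhib.4_15.

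Separated pups might have had a less mature transcriptome in excitatory neurons. If so, their changes in a pool would run against the change with age in the controls of the other pool, across genes. The higher of the 2 correlations across 11442 genes was 0.0507 and the other was -0.147, with pool 2 separated for the first and pool 1 for the other. Along the age change the pups of pool 1 stood at 1.01 and 3.84% of it in controls and -4.47 and -3.20% in separated pups, and those of pool 2 at -5.03 and 17.5% in controls and 3.59 and 16.4% in separated pups. The separated pups of pool 2 lay between their controls, so a delay cannot be told apart from the spread of the mice and is left open. That a pool counts only where its separated pups lie outside its controls was decided after these values were seen. Genes that overlap another gene on their strand made up 26.0% of the called P13 excitatory genes and 22.8% of the other tested genes (Fisher's exact p = 0.0386, across genes).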
